A study of Homo sapiens with 8 samples.

How the data were processed

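The data came from 8 microarrays, each hybridised with RNA from 1 xenograft condition, so that every combination of 3 factors was measured once. The factors were the cell line, MCF7 or its tamoxifen-resistant derivative MCF7(TAM-R), called TAM-R here; the hormone given to the mice, tamoxifen or estrogen; and AMD3100, an antagonist of the chemokine receptor CXCR4, given or not. Per the labels' protocols, athymic nude mice with xenografts received 500 µg of tamoxifen on 5 days per week or an estrogen pellet of 1.7 mg with release over 90 days. AMD3100 was released from a solution of 25 mg/ml at 0.25 µl per hour, per the labels' protocols. Total RNA was isolated from cell pellets with the RNeasy kit, and cRNA was amplified from 500 ng of it with GeneChip IVT Express kits and labelled with biotin, per the labels' protocols.

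The values were normalised with GCRMA, per the submitters' processing notes, which give no version. The deposited values were an intensity per probe set on a linear scale, as the values themselves showed: they ran from 2.24 to 71085 over 54675 probe sets. The column medians were 8.09 for MCF7 on tamoxifen, 7.90 for MCF7 on tamoxifen with AMD3100, 7.81 for TAM-R on tamoxifen and 8.87 for TAM-R on tamoxifen with AMD3100. On estrogen they were 7.80 for MCF7, 8.09 for MCF7 with AMD3100, 7.71 for TAM-R and 7.91 for TAM-R with AMD3100. The log2 of each intensity was taken with no pseudocount, and no further normalisation was applied.

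Probe sets were named through the platform annotation and checked by gene number against the RefSeq gene table of assembly GRCh38.p14. Of the 54675 probe sets, 41091 had 1 gene, 1801 had several genes, 62 were controls and 11721 had no gene in the annotation. The gene number of 41037 probe sets matched the RefSeq table, and 0 symbols changed. Probe sets with several genes or none were left out. Across 8 arrays, the median correlation of probe sets of the same gene was 0.531, against 0.102 for shuffled pairs. In 11 consecutive control probe sets the values appeared displaced by 1 place against their names, and these were not used; RNA quality was read from the actin, hybridisation and poly-A controls outside that stretch.

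Each gene was represented by the probe set with the highest mean, and genes with a log2 level of at least 5 in at least 2 arrays were tested, 10388 of 19775 genes or 52.5%. The effect of each factor was fitted with limma 3.58.1 in R 4.3.3 as an additive model of the 3 factors over all 8 arrays, with moderated variances that follow a trend on the mean level. That left 4 residual degrees of freedom, or 3 in models with 1 interaction. An alternative model with all 2-way interactions leaves only the 3-way term of the factors as residual. Because no combination was replicated, each p-value measures a difference against the spread between these arrays, which holds both array noise and any interaction of the factors. The adjusted p is the Benjamini-Hochberg value over the genes tested, and genes with an adjusted p under 0.05 were called. Differences are on the log2 scale with a standard error, and means of a factor level cover 4 arrays. The number of arrays limits the precision. Comparisons of a single array with another carry no p-value.

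The gene lists were estrogen-induced genes, cell cycle genes, CXCR4 and AHR pathway members, breast stem and progenitor cell markers, luminal and basal epithelial genes, mesenchymal transition genes, growth factor receptors and adaptors, and cholesterol synthesis genes. Others were interferon-stimulated, antigen presentation, hypoxia and glycolysis, unfolded protein and amino acid stress, immediate early, metallothionein, oxidative phosphorylation and ribosomal protein genes. Lists of AHR target genes and of fibroblast, endothelial, leukocyte and macrophage, adipocyte, muscle and erythroid markers had fewer than 5 measured genes and were not tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 51 tests for the 3 effects and over 17 tests for the line by AMD3100 interaction, with an estimated correlation and the fry test beside it. Fry gave an adjusted p of 0.413 or more for each list in the 3 effects and 0.694 or more in the interaction. In the 3 effects the estimated correlation was 0.66 for cell cycle, 0.81 for hypoxia and glycolysis and 0.88 for interferon-stimulated genes. The list calls therefore rest on the preset value. Camera compares a list with all other genes, so its direction opposed the sign of the list's median in 10 of 68 tests, 0 of which were called. For single pairs of arrays, the median of a list was placed among 10000 random lists of equal size matched on mean level in 20 bins.

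The model, the lists, the level filter, the thresholds and the rule for named genes were chosen before the data were examined. For each effect, the named genes were the 10 largest increases and 10 largest decreases among called genes with the same sign in all 4 matched pairs of arrays. Where fewer were called, the rule filled the list with genes of the same sign in all 4 pairs, ranked by the smallest of the 4 differences, given as values only. For each list up to 4 members with the lowest p were named. For each single AMD3100 comparison the rule took the 5 largest differences in each direction among genes at 7 or more in the higher array, and 16 genes, among them CXCR4, CXCL12, AHR and PGR, were always reported. Called interaction genes would have been named too.

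The alternatives were no level filter, a level of 7, values under 4 raised to 4, the mean of all probe sets of a gene, quantile normalisation again, arrays shifted to the same median, other variance settings, other models, and leaving out each array in turn. Array quality weights, a covariate for the actin gap and a term for the 3 arrays with the lowest hybridisation controls were added after the data had been seen. The term leaves 1 tamoxifen array for the hormone effect, so its hormone values test nothing and enter only the totals of changed and unchanged values. The procedure was tested on simulated arrays for the line effect, with 200 changed genes among 10388 in each of 10 runs. It recovered 42.8% of genes changed by 1 on the log2 scale, 94.2% of those changed by 2, 99.8% by 3 and 100% by 4, with 5.6% false among called genes. The simulated noise was independent between genes, with no hormone, AMD3100 or interaction effect. These rates therefore do not carry over to correlated genes, interactions or an array of poor quality. Tables were prepared with pandas 2.3.3 and NumPy 2.4.6 in Python 3.11.15, and plots drawn with Matplotlib 3.10.9.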

Results

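Expression was measured in MCF7, an estrogen receptor positive human breast cancer cell line, and in its tamoxifen-resistant derivative TAM-R, grown as xenografts in mice. The series title concerns CXCR4 activation, stem cells and AHR, the aryl hydrocarbon receptor, in tamoxifen-resistant cells. The 8 arrays held 1 array for each of the 8 combinations of line, hormone and AMD3100, so each level of a factor had 4 arrays and no combination had a replicate. Between 31.8% and 34.0% of the probe sets of an array had a log2 level of 5 or more. Correlations between arrays over all probe sets, which are not independent replicates, ran from 0.96 to 0.991.

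The first principal component, with 38.15% of the variance, set 3 of the 4 estrogen arrays, at scores of 42.4 to 48.0, apart from the 4 tamoxifen arrays, at -40.4 to -19.8. TAM-R on estrogen without AMD3100 lay at -10.8, and its closest array was TAM-R on tamoxifen without AMD3100, with a correlation of 0.991. The second component, with 27.13% of the variance, separated MCF7, at 6.12 to 47.1, from TAM-R, at -46.9 to -12.8.

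**Figure D1:**
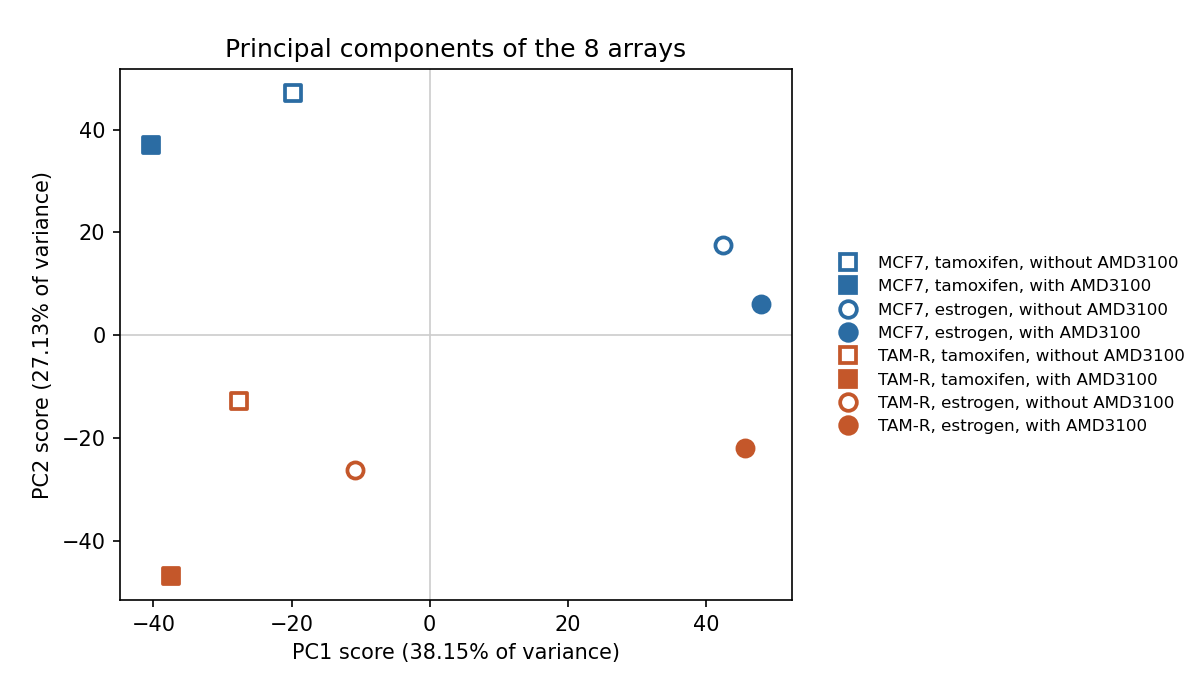
Scores of the 8 arrays on the first and the second principal component, without units; each point is 1 array, blue for MCF7 and orange for TAM-R, squares for tamoxifen and circles for estrogen, filled with AMD3100. TAM-R on estrogen without AMD3100 lies at -10.8 on the first component, between the tamoxifen arrays and the other estrogen arrays.

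Control measurements differed between arrays. The ratio of the 3′ to the 5′ actin probe set, which rises when RNA is degraded, was 23.6 in TAM-R on tamoxifen with AMD3100 and between 3.47 and 9.36 in the other 7 arrays. Mean hybridisation controls, added at a fixed amount, were lowest in 3 of the 4 tamoxifen arrays, at 8.94 to 9.67 on the log2 scale. They were 13.06 in TAM-R on tamoxifen with AMD3100 and between 10.82 and 12.13 on estrogen. Poly-A spikes were highest in TAM-R on tamoxifen with AMD3100, at 11.40, and MCF7 on estrogen with AMD3100, at 10.55. They were 6.86 to 8.77 in the other 6 arrays. Some skeletal muscle genes stood out in the same 2 arrays. ACTA1, muscle actin, was at 7.46 in the former and 8.41 in the latter, against at most 5.89 in the other 6. MYL11, a myosin light chain, was at 9.90 and 10.27. The 9 muscle markers chosen beforehand had a median AMD3100 difference of 0.075 in TAM-R on tamoxifen and 0.49 in MCF7 on estrogen.

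**Figure D2:**
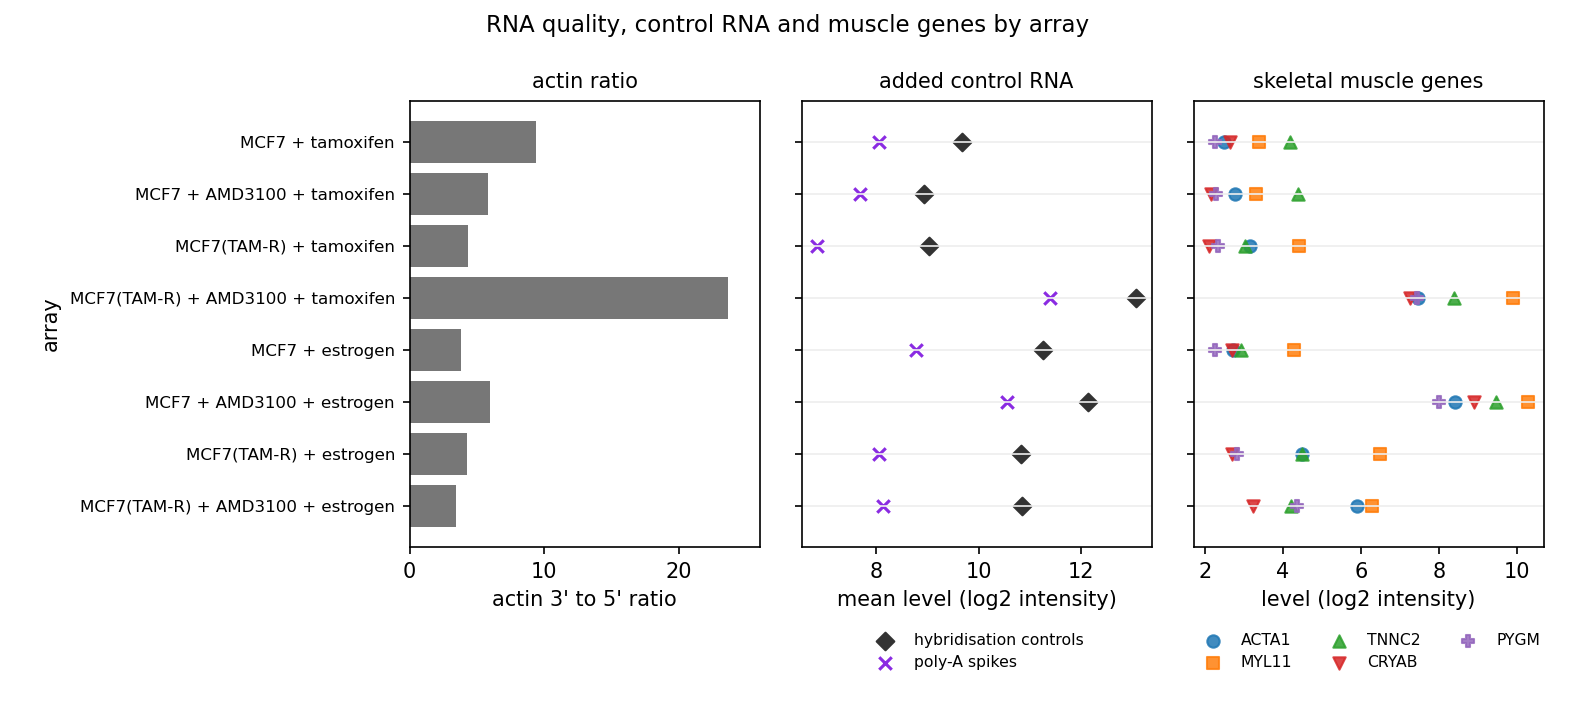
The actin 3′ to 5′ ratio (bars, linear scale), the mean log2 level of hybridisation controls and poly-A spikes, and the log2 level of 5 skeletal muscle genes, with 1 line per array. TAM-R on tamoxifen with AMD3100 has the highest actin ratio, 23.6, and these 5 muscle genes stand out there and in MCF7 on estrogen with AMD3100. They were picked as the 5 largest AMD3100 increases in the latter. The 9 muscle markers chosen beforehand had a median AMD3100 difference of 0.075 in TAM-R on tamoxifen and 0.49 in MCF7 on estrogen.

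The first comparison asked how the resistant line differed from its parent. FRAS1, a basement membrane protein, rose by 5.92 ± 0.32 (log2, SE, 4 arrays against 4; adjusted p = 0.000244) in TAM-R, from a mean of 3.23, near the lowest values on the arrays, so this is a lower limit. NIBAN1, a stress-response gene, rose by 5.24 ± 0.33, KCNE4, a potassium channel subunit, by 4.93 ± 0.49, and HTR2C, a serotonin receptor, by 3.91 ± 0.37. PRKACB, a catalytic subunit of protein kinase A, rose by 3.87 ± 0.43, and SOX2, a transcription factor of stem cells, by 3.83 ± 0.46 (adjusted p = 0.0109). RIMS2, SLIT1, VIL1 and TSPAN2 rose by 3.07 to 3.82. FGG, the gamma chain of fibrinogen, fell by 7.44 ± 0.30 on the log2 scale (adjusted p = 8.53e-05), from a mean of 10.47 to 3.04, again near the lowest values. The lower mean was also under 4 for KCNE4, RIMS2, SLIT1, VIL1 and TSPAN2.

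CTSC, a lysosomal protease, fell by 4.34 ± 0.23 on the log2 scale, and UGT2B28, which conjugates steroids, fell by 4.01 ± 0.37. SLC30A8, a zinc transporter, fell by 3.69 ± 0.33, SPARC, a matrix protein, fell by 3.33 ± 0.36, and SULF1, which trims heparan sulfate, fell by 3.15 ± 0.23. CXCL12, the ligand of CXCR4, fell by 3.20 ± 0.65 on the log2 scale (adjusted p = 0.0472), from a mean of 7.58 in MCF7 to 4.38 in TAM-R. MGP, TNIK and DYRK4 differed by -3.13, -2.93 and -2.91 and were called too. The lower mean was under 4 for CTSC, SLC30A8, TNIK and DYRK4. CXCR4 itself differed by 0.78 ± 0.31 (adjusted p = 0.214), with a mean of 7.74 in MCF7 and 8.52 in TAM-R. In all, 273 of 10388 genes were called, 149 higher and 124 lower, and 273 of them had the same sign in all 4 matched pairs of arrays.

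Leaving out 1 array left 26 called genes without MCF7 on tamoxifen, 27 without TAM-R on tamoxifen, 23 without MCF7 on estrogen, 26 without MCF7 on estrogen with AMD3100, 82 without TAM-R on estrogen, 175 without TAM-R on tamoxifen with AMD3100 and 469 without TAM-R on estrogen with AMD3100. FRAS1, NIBAN1, KCNE4, HTR2C, PRKACB, FGG, CTSC, UGT2B28, SLC30A8, SPARC and SULF1 were called in 8 of 8 such fits. RIMS2 was called in 7, SOX2 in 5, DYRK4 in 4, VIL1, TSPAN2 and TNIK in 3, SLIT1 in 2, and CXCL12 and MGP in 1, with a highest adjusted p of 0.174 for CXCL12. The call count was 18 with no level filter, 144 with the mean of all probe sets, 632 with all 2-way interactions, 113 with the line alone, and 1125 with array quality weights.

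Estrogen-induced genes fell as a list in TAM-R, with a median of -0.44 and 31 of 35 measured genes negative (camera adjusted p = 0.000133; adjusted p = 0.87 with an estimated correlation). TFF3, a secreted mucosal peptide, fell by 1.03 ± 0.15 on the log2 scale (adjusted p = 0.0184), CA12, a carbonic anhydrase, fell by 1.34 ± 0.25 (adjusted p = 0.0409), and CXCL12 was the other called member. That made 3 of 35 over all genes and 3 adjusted over the list alone. The fall was uneven over the pairs. The list's median was -0.87 on tamoxifen with AMD3100, a pair that holds the array with the highest actin ratio. It was -0.84 on estrogen without AMD3100, where the TAM-R array lay close to TAM-R on tamoxifen. It was only -0.015 on tamoxifen without AMD3100, with 16 of 35 positive, and -0.19 on estrogen with AMD3100, with 14 of 35 positive. PGR, the progesterone receptor, differed by -0.94 ± 0.33 (adjusted p = 0.173) and GREB1 by -1.12 ± 0.45 (adjusted p = 0.23), so neither passed the test. ESR1, the estrogen receptor itself, differed by 0.10 ± 0.40 (adjusted p = 0.922).

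Hypoxia and glycolysis genes fell as a list, with a median of -0.95 and 20 of 22 negative (camera adjusted p = 0.000127; adjusted p = 0.87 with an estimated correlation). They were lower in 3 of 4 pairs, with medians of -1.61 and -0.81 on tamoxifen without and with AMD3100 and -1.79 on estrogen, and opposite on estrogen with AMD3100, at 0.42 with 16 of 22 positive. No member passed over all genes, and 1 rose and 1 fell adjusted over the list alone; P4HA2, a prolyl hydroxylase, differed by -1.28 ± 0.40, HK2, a hexokinase, by -0.82 ± 0.20, and ADM, adrenomedullin, by 1.34 ± 0.33. The hypoxia median was -1.46 without TAM-R on estrogen with AMD3100. The 6 measured metallothionein genes, which bind metals, had a median of -0.81 and fell as a list (camera adjusted p = 0.0015; adjusted p = 0.87 with an estimated correlation). Of these, 5 fell adjusted over the list alone and 0 over all genes, with MT2A at -1.13 ± 0.35 and MT1X at -1.05 ± 0.35. Interferon-stimulated genes fell as a list, with a median of -1.13 and 23 of 26 negative (camera adjusted p = 0.000628; adjusted p = 0.87 with an estimated correlation), but 0 of 26 passed by either adjustment and the list was lower in 2 of 4 pairs. Without MCF7 on tamoxifen with AMD3100 its median was -0.15 (adjusted p = 0.0798), and without TAM-R on tamoxifen with AMD3100, the array with the highest actin ratio, it was -0.27 (adjusted p = 0.098).

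Single members of other lists also passed in TAM-R. ERBB4, a receptor of the epidermal growth factor family, rose by 2.06 ± 0.42 (adjusted p = 0.049), 1 of 16 growth factor receptors and adaptors, of which 4 rose and 1 fell adjusted over the list alone. ATP5F1A, a subunit of ATP synthase, rose by 1.31 ± 0.17 (adjusted p = 0.0139), and the immediate early gene EGR1 fell by 1.27 ± 0.25 on the log2 scale (adjusted p = 0.0439). Among breast stem and progenitor cell markers, SOX2 was the 1 of 9 called, and SOX2 rose and SOX9, at -1.15 ± 0.31, fell adjusted over the list alone. CD44 differed by -0.50 ± 0.25 (adjusted p = 0.319) and CD24 by 0.52 ± 0.27 (adjusted p = 0.349). The lists of cell cycle, stem and progenitor, luminal, basal, mesenchymal, growth factor receptor, cholesterol synthesis, antigen presentation, stress, immediate early, oxidative phosphorylation and ribosomal genes and of CXCR4 and AHR pathway members were not called, with adjusted p from 0.114 to 0.934.

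The hormone comparison asked how tumours on estrogen differed from tumours on tamoxifen. Cell cycle genes rose as a list on estrogen, with a median of 0.97 and 38 of 40 positive (camera adjusted p = 1.36e-08; adjusted p = 0.87 with an estimated correlation). MKI67, a marker of dividing cells, rose by 2.26 ± 0.40 (log2, SE, 4 arrays against 4; adjusted p = 0.049), PLK1, a mitotic kinase, by 2.14 ± 0.38, KIF20A, a mitotic motor, by 1.53 ± 0.29 and CENPF, a kinetochore protein, by 1.28 ± 0.25. These 4 of 40 passed over all genes and 27 rose adjusted over the list alone. The median rise was 1.13 in MCF7 and 1.28 in MCF7 with AMD3100, 1.42 in TAM-R with AMD3100 and 0.049 in TAM-R without AMD3100.

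MCM10, which acts in DNA replication, rose by 2.35 ± 0.39, PDLIM3 and SYNPO2, both actin-associated proteins, rose by 3.26 ± 0.66 and 2.82 ± 0.45, and HBE1, a globin, rose by 2.72 ± 0.44. BAGE2, DLC1, KCNQ1OT1, MARS2 and NAA15 rose by 2.19 to 2.56. SOX2 fell by 2.26 ± 0.46 on the log2 scale (adjusted p = 0.0497) on estrogen, and UGT2B28 fell by 2.02 ± 0.37. C7orf57 was called at -3.79, FAM81B at -3.24, GASK1B at -2.51, ATP8A1, a phospholipid flippase, at -2.46, SGMS1 at -1.97, MIGA1 at -1.94, and SKIC3 and TSPAN12 at -1.84. NR4A2, an immediate early gene, fell by 1.56 ± 0.28 on the log2 scale (adjusted p = 0.049), and UQCRC1, of the respiratory chain, rose by 0.89 ± 0.15 (adjusted p = 0.049). The lower mean was under 4 for PLK1, PDLIM3, BAGE2, MARS2, C7orf57 and FAM81B.

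Of 10388 genes, 260 were called, 153 higher and 107 lower on estrogen, with a lowest adjusted p of 0.049, shared by most of them. The median of all genes was 0.16 higher on estrogen; after quantile normalisation 112 of 397 called genes were higher, and with arrays shifted to the same median 90 of 482, so the balance of rises and falls depended on the scaling. The count was 0 without MCF7 on tamoxifen, MCF7 on tamoxifen with AMD3100, TAM-R on tamoxifen, MCF7 on estrogen, MCF7 on estrogen with AMD3100 or TAM-R on estrogen with AMD3100, in each case 1 at a time. It was 464 without TAM-R on tamoxifen with AMD3100 and 1287 without TAM-R on estrogen, the array close to TAM-R on tamoxifen. A batch of the 3 tamoxifen arrays with low hybridisation controls could not be corrected for, since a term for them leaves only TAM-R on tamoxifen with AMD3100, with the actin ratio of 23.6, to compare with the estrogen arrays. Each named hormone gene was called in 1 or 2 of the 8 fits with an array left out, and the count was 0 with no level filter, with no variance trend or with matched pairs, 8 with the mean of all probe sets and 19 with the actin gap as a covariate.

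Interferon-stimulated genes fell as a list on estrogen, with a median of -1.32 and 24 of 26 negative (camera adjusted p = 2.23e-08; adjusted p = 0.87 with an estimated correlation), and 0 of 26 passed by either adjustment. ISG15, a ubiquitin-like protein, differed by -1.70 ± 0.44 and DDX60 by -1.97 ± 0.53. The list's median was -1.90 in MCF7, -3.37 in MCF7 with AMD3100, -0.55 in TAM-R and 0.54 in TAM-R with AMD3100. Without MCF7 on tamoxifen with AMD3100 it was -0.73. Antigen presentation genes fell as a list, with a median of -0.71 (camera adjusted p = 0.0015; adjusted p = 0.87 with an estimated correlation), with HLA-B at -1.28 ± 0.45. That median was -0.53 (adjusted p = 0.0938) with no level filter; it was -0.35 without MCF7 on tamoxifen with AMD3100. Luminal epithelial genes fell as a list, with a median of -0.29 (camera adjusted p = 0.0153; adjusted p = 0.87 with an estimated correlation), with 1 of 19 lower adjusted over the list alone, MUC1, a mucin, at -1.26 ± 0.29. Without TAM-R on tamoxifen the luminal median was -0.20 (adjusted p = 0.05), without MCF7 on tamoxifen -0.44, without MCF7 on tamoxifen with AMD3100 0.056 and without MCF7 on estrogen -0.19. It was -0.21 (adjusted p = 0.513) with no level filter and -0.048 (adjusted p = 0.066) with the mean of all probe sets.

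Oxidative phosphorylation genes rose as a list, with a median of 0.36 and 20 of 22 positive (camera adjusted p = 0.032; adjusted p = 0.87 with an estimated correlation), 4 of them adjusted over the list alone and UQCRC1 over all genes. The call ended without TAM-R on tamoxifen with AMD3100 (median 0.20, adjusted p = 0.244), MCF7 on estrogen with AMD3100 (0.36, adjusted p = 0.0753) or TAM-R on estrogen with AMD3100 (0.30, adjusted p = 0.206). It also ended with the mean of all probe sets (0.25, adjusted p = 0.26), array quality weights (0.28, adjusted p = 0.203) and the actin gap as a covariate (0.098, adjusted p = 0.636). Estrogen-induced genes had a median of 0.73, and camera gave an adjusted p of 0.141; 0 of 35 passed over all genes, while 17 rose and 3 fell adjusted over the list alone. OLFM1 differed by 1.47 ± 0.32, HSPB8, a small heat shock protein, by 2.03 ± 0.45, and MYC by 1.75 ± 0.43. PGR differed by 1.24 ± 0.33 (adjusted p = 0.067). AHR differed by -1.22 ± 0.40 (adjusted p = 0.0965), and ACKR3, a second receptor of CXCL12, differed by -1.04 ± 0.39 (adjusted p = 0.123). The other lists were not called for hormone, with adjusted p from 0.259 to 0.87.

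**Figure D3:**
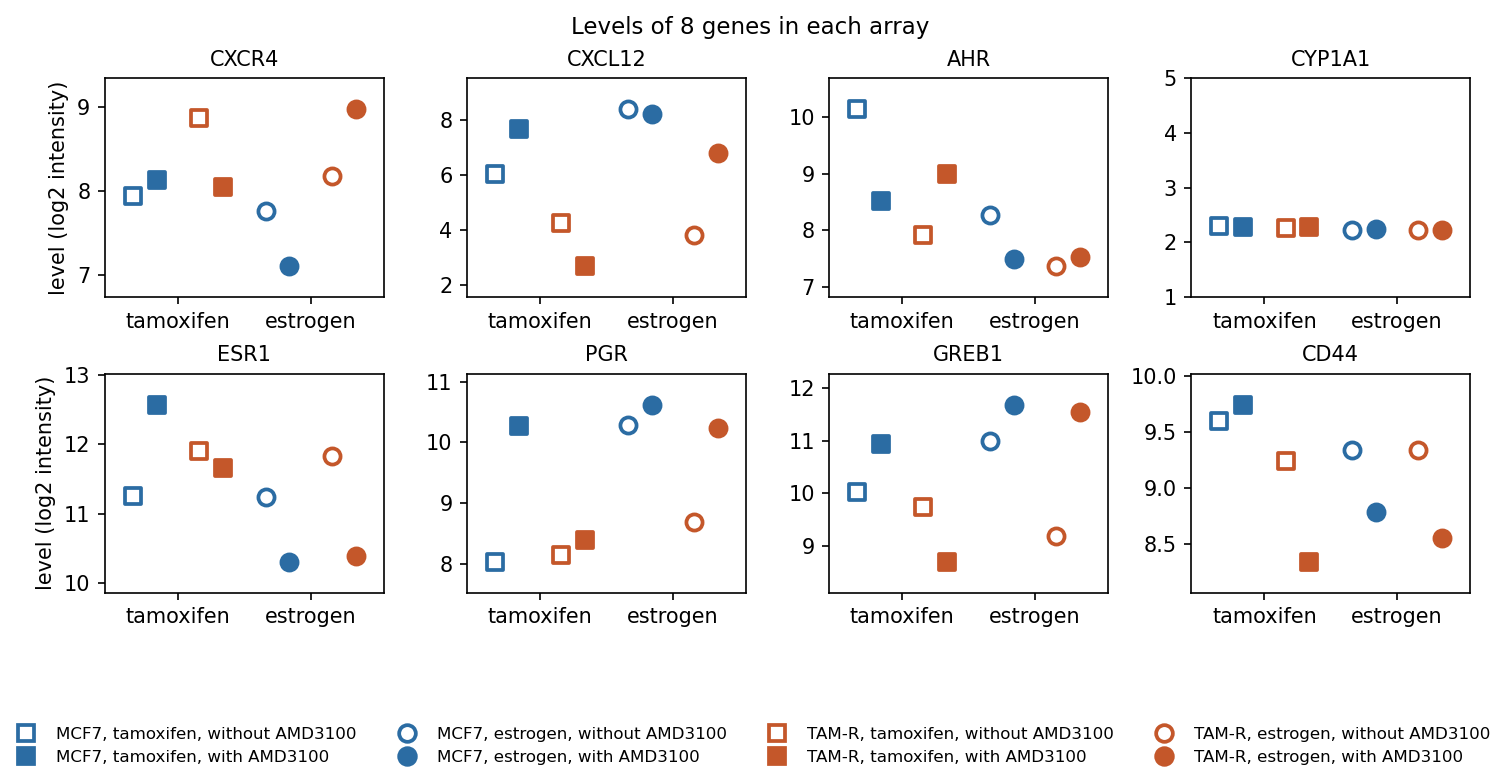
Log2 level of 8 genes in each of the 8 arrays, grouped by hormone; each point is 1 array, blue for MCF7 and orange for TAM-R, filled with AMD3100. PGR in TAM-R on estrogen is at 8.68 without AMD3100 and at 10.23 with it, and CYP1A1 lies between 2.22 and 2.29 in all 8 arrays.

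The AMD3100 comparison asked what blocking CXCR4 did to the tumours. No gene was called across both lines and both hormones: limma found 0 of 10388, with a lowest adjusted p of 0.763, and 569 genes had an unadjusted p under 0.05 where chance gives 519. The genes with the most even differences were lower with AMD3100: CRISP3 at -2.55 ± 0.54, SERHL2 at -1.71 ± 0.44, MSMB at -1.61 ± 0.31, MUCL1, a small breast mucin, at -1.46 ± 0.24, TM4SF1 at -1.36 ± 0.24 and CPE, a carboxypeptidase, at -1.27 ± 0.25. MMEL1, CYP4B1, RIIAD1 and DHRS12 lay between -1.51 and -0.95. On the other side were INHBC at 1.31 ± 0.47, ENO3, the enolase of muscle, at 1.20 ± 0.37, RUFY3, PSMD6-AS2, DPP9 and FTX at 0.93 or more, and CNTROB, ZNF793, FANCG and ZMYM1 at 0.60 to 0.86. The lower mean was under 4 for MMEL1 and ENO3.

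PGR differed by 1.09 ± 0.33 with AMD3100, higher in 4 of 4 pairs (adjusted p = 0.763). CXCR4, the target of the drug, differed by -0.12 ± 0.31 (adjusted p = 0.916), CXCL12 by 0.73 ± 0.65 (adjusted p = 0.785), AHR by -0.30 ± 0.40 (adjusted p = 0.851), and ARNT, its partner, by 0.094 ± 0.20 (adjusted p = 0.902). That CXCR4 value came from the probe set with the highest mean level. The other 2 fell from 7.14 to 3.85 and from 7.35 to 3.97 with AMD3100 in TAM-R on tamoxifen, whose array with AMD3100 had the highest actin ratio. They also fell in MCF7 on estrogen, from 5.99 to 3.97 and from 5.91 to 4.83, and rose in MCF7 on tamoxifen, from 4.75 to 6.13 and from 5.51 to 6.10, and in TAM-R on estrogen, from 6.75 to 7.46 and from 6.86 to 6.99. The mean of all CXCR4 probe sets differed by -0.62 (adjusted p = 0.777) over the 4 pairs. ESR1 differed by -0.33 ± 0.40, TFF1, near the top of the scale at 15.46 to 15.72 in all arrays, by -0.014 ± 0.11, and SOX2 by -1.35 ± 0.46. Of the AHR target genes, 3 of 12 were measured, NQO1 at -0.31 ± 0.20, SLC7A5 at 0.17 ± 0.35 and TIPARP at 0.016 ± 0.21; CYP1A1, at 2.22 to 2.29, lay near the lowest values of the arrays. AHRR, CYP1B1, ALDH1A1 and ALDH1A3 did not pass the level filter either. CYP1B1 was higher with AMD3100 on estrogen, from 3.15 to 5.35 in MCF7 and from 3.07 to 3.90 in TAM-R. On tamoxifen it went from 3.22 to 3.15 and from 3.09 to 3.25. A further CYP1B1 probe set went from 2.80 to 5.55 and from 2.61 to 4.56 on estrogen. Another stayed at 2.08 to 2.18 in all arrays. These are single arrays, mostly near the lowest values.

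Estrogen-induced genes rose as a list with AMD3100, with a median of 0.22, higher in 2 of 4 pairs (camera adjusted p = 0.000294; adjusted p = 0.87 with an estimated correlation), and cell cycle genes by 0.13, also in 2 of 4 pairs (camera adjusted p = 0.0094; adjusted p = 0.87 with an estimated correlation). Oxidative phosphorylation genes fell, with a median of -0.29 and 22 of 22 negative (camera adjusted p = 0.000628; adjusted p = 0.87 with an estimated correlation), as did ribosomal protein genes, at -0.19 and 17 of 17 negative (camera adjusted p = 0.0019; adjusted p = 0.87 with an estimated correlation). Luminal genes fell, with a median of -0.28 (camera adjusted p = 0.017; adjusted p = 0.87 with an estimated correlation) as did hypoxia and glycolysis genes, at -0.41 (camera adjusted p = 0.0388; adjusted p = 0.87 with an estimated correlation). No member of these lists passed over all genes, and adjusted over the list alone 1 hypoxia gene fell, ADM at -1.55 ± 0.33. Among random lists of similar level, ribosomal genes lay at percentiles of 17.6 in MCF7 on tamoxifen, 34.5 in TAM-R on tamoxifen, 43.0 in MCF7 on estrogen and 12.8 in TAM-R on estrogen, so they stood out in no single pair. Their largest fall, -0.57, was in TAM-R on tamoxifen, whose array with AMD3100 had the highest actin ratio. Oxidative phosphorylation genes also fell most there, at -0.69, and lay at percentiles of 0.84, 4.18, 2.95 and 78.2 in the same order. The other lists were not called, with adjusted p from 0.118 to 0.852.

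Single arrays decided 3 of these 6 list calls. The cell cycle median was -0.13 (adjusted p = 0.106) without TAM-R on estrogen, -0.028 (adjusted p = 0.959) without TAM-R on estrogen with AMD3100 and 0.12 (adjusted p = 0.0753) without MCF7 on estrogen with AMD3100. Where its call stayed, the cell cycle median was 0.22 to 0.31 without MCF7 on tamoxifen with AMD3100, TAM-R on tamoxifen or TAM-R on tamoxifen with AMD3100. The luminal median was -0.46 without MCF7 on tamoxifen with AMD3100, -0.17 (adjusted p = 0.16) without TAM-R on tamoxifen with AMD3100 and -0.23 (adjusted p = 0.0968) without TAM-R on estrogen. The hypoxia median was -0.037 (adjusted p = 0.698) without MCF7 on tamoxifen, -0.14 (adjusted p = 0.86) without MCF7 on tamoxifen with AMD3100 and -0.19 (adjusted p = 0.16) without TAM-R on tamoxifen with AMD3100. It was -0.42 (adjusted p = 0.116) without MCF7 on estrogen and -0.24 (adjusted p = 0.232) without MCF7 on estrogen with AMD3100, and it was -0.73 without TAM-R on estrogen and -0.89 without TAM-R on estrogen with AMD3100, where the call stayed. The other 3 calls stayed with smaller or larger medians. Estrogen-induced genes were at 0.13 without MCF7 on tamoxifen, 0.36 without MCF7 on estrogen and 0.32 without MCF7 on estrogen with AMD3100. Oxidative phosphorylation genes were at -0.17 without TAM-R on tamoxifen and -0.13 without TAM-R on tamoxifen with AMD3100, and ribosomal genes at -0.074 without the latter array.

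Other settings ended the same 3 calls. The luminal median was -0.21 (adjusted p = 0.194) with the mean of all probe sets, -0.25 (adjusted p = 0.0522) with array quality weights and -0.18 (adjusted p = 0.0792) with the actin gap. The hypoxia median was -0.26 (adjusted p = 0.194) with the mean of all probe sets and -0.25 (adjusted p = 0.0705) with the actin gap. The cell cycle call ended with no level filter (0.13, adjusted p = 0.181).

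A further comparison asked whether AMD3100 acted differently in the resistant line. Hypoxia and glycolysis genes differed most between the lines: the AMD3100 difference in TAM-R minus that in MCF7 had a median of 1.59, with 22 of 22 positive (camera adjusted p = 1.27e-17; adjusted p = 0.572 with an estimated correlation). With AMD3100 these genes had a median of -1.29 in MCF7 on tamoxifen, -0.63 in MCF7 on estrogen and -0.81 in TAM-R on tamoxifen, against 1.40 in TAM-R on estrogen. Members with the lowest p were PFKFB3, a regulator of glycolysis, at 2.10 ± 0.53, VEGFA, the angiogenic factor, at 2.47 ± 0.79, SLC2A1, a glucose transporter, at 1.86 ± 0.62, and ADM at 1.40 ± 0.47. Basal epithelial genes had a median of 1.42, with 5 of 6 positive (camera adjusted p = 0.000104; adjusted p = 0.506 with an estimated correlation), among them KRT5, a basal keratin, at 2.70 ± 0.91 and CAV1 at 1.87 ± 0.68. These 2 calls held with each array left out, and that of basal genes ended with no level filter (median 1.38, adjusted p = 0.211). The TAM-R pair on tamoxifen holds the array with the highest actin ratio, and that on estrogen the array close to TAM-R on tamoxifen. Leaving out either array left the comparison resting on the other, so these fits do not show independence from both. The hypoxia median was 0.98 without MCF7 on tamoxifen, 0.91 without TAM-R on estrogen and 0.56 (adjusted p = 0.001) without TAM-R on estrogen with AMD3100.

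Antigen presentation genes had a median of -0.95 for this difference (camera adjusted p = 0.0084; adjusted p = 0.687 with an estimated correlation), with HLA-F at -0.95 ± 0.39, luminal genes -0.49 (camera adjusted p = 0.0358; adjusted p = 0.687 with an estimated correlation) and ribosomal genes -0.30 (camera adjusted p = 0.0358; adjusted p = 0.742 with an estimated correlation). Cell cycle genes had a median of 0.20 (camera adjusted p = 0.000941; adjusted p = 0.742 with an estimated correlation), and mesenchymal genes 0.22 (camera adjusted p = 0.0358; adjusted p = 0.572 with an estimated correlation), with FN1, fibronectin, at 1.72 ± 0.38. Stress genes had a median of 0.18 (camera adjusted p = 0.0149; adjusted p = 0.687 with an estimated correlation), with HSP90B1, a chaperone, at 1.64 ± 0.32. Adjusted over the list alone, 1 mesenchymal gene and 1 stress gene rose, and 0 passed over all genes. The other 9 lists were not called, with adjusted p from 0.344 to 0.935.

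Each of these 6 calls ended with some array left out. Without TAM-R on tamoxifen with AMD3100, the array with the highest actin ratio and with muscle genes, the medians were -0.82 for antigen presentation (adjusted p = 0.416), -0.35 for luminal (adjusted p = 0.557), -0.28 for mesenchymal (adjusted p = 0.466) and -0.081 for ribosomal genes (adjusted p = 0.915). Without MCF7 on tamoxifen with AMD3100 they were -0.15 (adjusted p = 0.431), -0.18 (adjusted p = 0.267), -0.091 (adjusted p = 0.269) and -0.21 (adjusted p = 0.2), and the cell cycle median was 0.13 (adjusted p = 0.267). Without MCF7 on estrogen they were -0.70 (adjusted p = 0.0838), -0.54 (adjusted p = 0.31), 0.077 (adjusted p = 0.18) and -0.27 (adjusted p = 0.329). Without TAM-R on estrogen the medians were -0.64 for antigen presentation (adjusted p = 0.122), -0.28 for luminal (adjusted p = 0.0795), 0.32 for mesenchymal (adjusted p = 0.0706) and -0.41 for cell cycle genes (adjusted p = 0.0114). Without TAM-R on estrogen with AMD3100 they were -0.25 for cell cycle (adjusted p = 0.812) and -0.10 for stress genes (adjusted p = 0.444). The ribosomal median was -0.24 (adjusted p = 0.45) without TAM-R on tamoxifen and -0.43 (adjusted p = 0.104) without MCF7 on estrogen with AMD3100, and the stress median was 0.066 (adjusted p = 0.14) without MCF7 on tamoxifen.

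Where these calls stayed, the cell cycle median ran from 0.06 without MCF7 on estrogen to 0.89 without TAM-R on tamoxifen. It was 0.32 without MCF7 on tamoxifen, 0.33 without MCF7 on estrogen with AMD3100 and 0.61 without TAM-R on tamoxifen with AMD3100. The mesenchymal median was 0.54 without MCF7 on tamoxifen, 0.15 without TAM-R on tamoxifen, 0.85 without MCF7 on estrogen with AMD3100 and 0.67 without TAM-R on estrogen with AMD3100. The stress median was 0.31 without TAM-R on tamoxifen with AMD3100, 0.27 without MCF7 on estrogen and 0.033 without TAM-R on estrogen. The antigen presentation median was -1.81 without MCF7 on estrogen with AMD3100, and the ribosomal median was -0.52 without TAM-R on estrogen with AMD3100.

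Other settings ended these interaction calls as well. With no level filter the adjusted p was 0.177 for cell cycle and stress genes and 0.053 for mesenchymal genes. With the mean of all probe sets it was 0.331 for luminal and 0.128 for ribosomal genes, and after quantile normalisation 0.0547 for luminal, 0.105 for mesenchymal and 0.118 for ribosomal genes. With array quality weights the calls of cell cycle (adjusted p = 0.0946), luminal (0.196), mesenchymal (0.196), antigen presentation (0.374) and ribosomal genes (0.0687) ended. Those of luminal, mesenchymal, antigen presentation and ribosomal genes ended with the actin gap (adjusted p = 0.188, 0.334, 0.166 and 0.334).

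**Figure D4:**
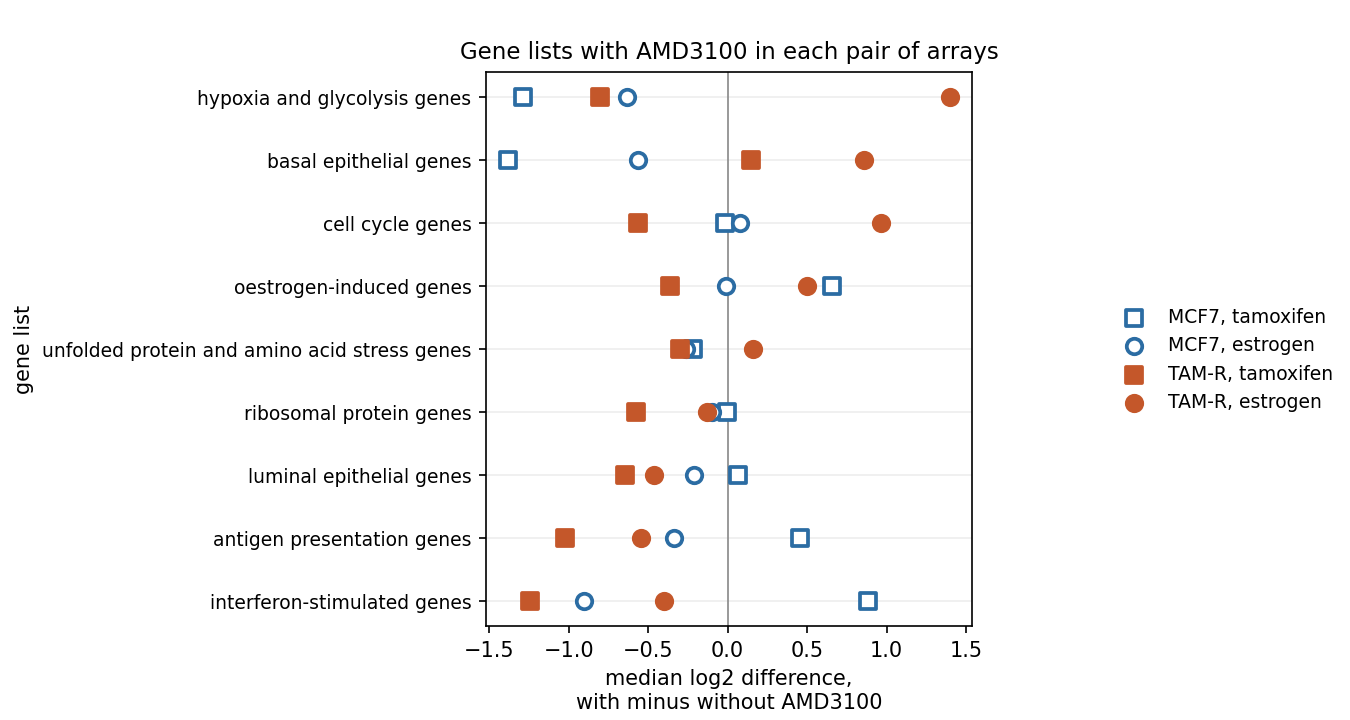
Median log2 difference with minus without AMD3100 for 9 gene lists in each of the 4 pairs of arrays; open blue symbols are MCF7 and filled orange symbols TAM-R, squares for tamoxifen and circles for estrogen. Hypoxia and glycolysis genes lie at 1.40 in TAM-R on estrogen and between -1.29 and -0.63 in the other 3 pairs.

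In single pairs of arrays, AMD3100 went with 2-fold differences of 941 genes in MCF7 on tamoxifen, 2000 in TAM-R on tamoxifen, 310 in MCF7 on estrogen and 1312 in TAM-R on estrogen. Each count was smaller with the mean of all probe sets, as given under the processing below. In MCF7 on tamoxifen the squamous and inflammatory genes S100A7, KRTDAP, S100A9 and S100A8 differed by -8.27, -7.99, -6.88 and -6.81, GJB2, a gap junction protein, by -5.87, and CDH11, a cadherin, by 3.06. HMCN1, LRFN5, IGSF5 and BRINP2 lay at 2.52 to 2.77. In TAM-R on tamoxifen KRTDAP and S100A7 differed by -6.17 and -4.26, DNAJB6, HERC6 and MAD2L2 by -4.14 to -3.70, and the probe set annotated Igk by 5.50. The other 4 named increases there were muscle genes, MYL11, TNNC2, CRYAB and PYGM, at 5.11 to 5.49, in the array with the highest actin ratio. The same muscle genes and ACTA1 made up the 5 largest increases in MCF7 on estrogen, at 5.70 to 6.54, with IFIT3, GPC3, UGT2B28, OLFML3 and ANKRD37 at -3.38 to -2.16.

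In TAM-R on estrogen STC1, a glycoprotein hormone, and ALDOC, a glycolytic aldolase, differed by 4.03 and 3.90 with AMD3100, as did SOX8 by 4.28 and LOC102723847 by 4.59, with RNF183 between STC1 and ALDOC. CDC20B was at -6.56, SERPINA6, the corticosteroid-binding globulin, at -5.62, Igk at -5.45, HOPX at -4.93 and TIMP3, an inhibitor of matrix proteases, at -4.82. The 40 cell cycle genes all lay higher there, with a median of 0.96, above 100% of random lists, and the estrogen-induced genes had a median of 0.50. The array without AMD3100 in this pair was close to TAM-R on tamoxifen, and its cell cycle genes were 0.049 higher than there. GREB1, which estrogen receptor induces, was at 9.18 without and 11.55 with AMD3100. Interferon-stimulated genes had medians of 0.88 in MCF7 on tamoxifen, -1.25 in TAM-R on tamoxifen, -0.91 in MCF7 on estrogen and -0.40 in TAM-R on estrogen. These are differences of 1 array from another, with no replicate check.

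Differences of 2 probe sets of the same gene, compared across 4305 genes, correlated at 0.742 for the AMD3100 pair of TAM-R on estrogen, 0.554 for MCF7 on tamoxifen, 0.246 for MCF7 on estrogen and 0.175 for TAM-R on tamoxifen. For the hormone pairs this correlation was 0.39 in MCF7, 0.557 in MCF7 with AMD3100, 0.0936 in TAM-R and 0.388 in TAM-R with AMD3100; for the line pairs it ran from 0.358 to 0.807. Across genes, which are not independent replicates, the AMD3100 differences of disjoint pairs of arrays correlated with a median r of 0.098 (-0.31 to 0.36 over 6 pairings), against 0.42 for line and 0.44 for hormone.

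No gene was called for any 2-way interaction when each was fitted alone. A model with all 2-way interactions together did call genes, as given under the processing below. Its residual spread is the 3-way term alone, so those counts are a weak check. With limma, 358 genes had an unadjusted p under 0.05 for line by AMD3100, 343 for line by hormone and 608 for hormone by AMD3100, where chance gives 519. The following genes were chosen after their values were seen. KRTDAP and S100A7 had the lowest p for hormone by AMD3100, at 9.12 ± 1.21 and 7.95 ± 1.11 (adjusted p = 0.794 for both): with AMD3100 KRTDAP went from 11.21 to 3.22 in MCF7 on tamoxifen and from 5.80 to 8.03 in MCF7 on estrogen. BST2, an interferon-induced membrane protein, was at 2.57 ± 0.42 and CCL5, a chemokine, at 2.68 ± 0.50 for line by hormone (adjusted p = 0.967 for both). CPB1, a carboxypeptidase, was at -4.09 ± 0.79 for line by AMD3100 (adjusted p = 0.947), at 6.31 and 6.69 in TAM-R without AMD3100 and at 2.23 to 2.54 in the other 6 arrays.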

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

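Except for the list tests of the line by AMD3100 interaction, the counts over other splits of the arrays, the correlation of probe sets of the same gene and the comparison of all genes with those lower with AMD3100, the tests in this part were chosen only after the results were seen.

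The AMD3100 response differed between the lines for 8 gene lists by camera with a preset correlation, and for 0 with an estimated one. The medians of TAM-R minus MCF7 were 1.59 for hypoxia and glycolysis, 1.42 for basal, 0.22 for mesenchymal, 0.20 for cell cycle and 0.18 for stress genes. They were -0.95 for antigen presentation, -0.49 for luminal and -0.30 for ribosomal genes.

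Other splits of the 8 arrays into 4 and 4 were fitted in the same models. For line, 1 of 33 splits, the real one, gave as many as 273 genes, and the highest other gave 6. For hormone, 1 of 33 splits gave as many as 260, and the highest other gave 29. The real split thus gave the most genes for line and for hormone. Each other split left the real effect in its residual spread, which lowers its count, so this comparison does not exclude chance. For AMD3100 and the 3 interactions the real count was 0, so that 33 of 33 and 32 of 32 splits had to give as many, with 1 as the highest other, and this decides nothing. At an unadjusted p under 0.05 in limma, 13 of 33 splits gave as many genes as the 569 of AMD3100. For line by AMD3100, 17 of 32 splits gave as many as 358, for line by hormone 18 gave as many as 343, and for hormone by AMD3100 12 gave as many as 608. Chance is not excluded for these 4 counts.

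TAM-R on estrogen without AMD3100 lay closest to TAM-R on tamoxifen, with a correlation of 0.9905. It correlated more with MCF7 on estrogen (0.982) and TAM-R on estrogen with AMD3100 (0.983) than with the other tamoxifen arrays (0.970 to 0.979). With MCF7 on estrogen with AMD3100 the correlation was 0.976, within the range of those tamoxifen arrays, so the order does not settle the hormone of this array. AMD3100 differences against it, such as a median of 0.96 for cell cycle genes, could be hormone differences. The same could hold for the 1.40 of hypoxia genes, though their hormone median was 0.40 and not called (camera adjusted p = 0.655). Poor RNA of that array is argued against, since its actin gap ranked 6 and its poly-A spikes 5 among the 8 arrays, highest first. An array that holds tamoxifen RNA stays open: over the 918 genes that differed 2-fold in both MCF7 hormone pairs, its signed difference from TAM-R on tamoxifen had a median of 0.45, but this was 0.72 over the 197 genes hardly changed in TAM-R with AMD3100 and 0.27 over the 482 that changed 2-fold there. A batch shared by arrays with low hybridisation controls could give that order. A smaller estrogen response of TAM-R without AMD3100 may also be the reason: the signed median was higher by 0.62 with AMD3100, but limma called 0 genes for the 3-way term (200 at an unadjusted p under 0.05), so it cannot be told apart from a wrong label.

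Many genes differed with AMD3100 in TAM-R on tamoxifen. Host muscle is argued against as the whole cause of the 1489 genes at 2-fold or lower, but only if MCF7 on estrogen with AMD3100 held as much muscle. In that array 6 of 6 muscle genes were higher than here. All of them but ENO3 were picked as the largest AMD3100 increases in MCF7 on estrogen, so the choice itself favoured this. Of the 9 muscle markers chosen beforehand, CKM, MYH7, MB and TTN were lower there than here and the rest higher. MCF7 on estrogen with AMD3100 also had high poly-A spikes, at 10.55 against 11.40 here, which limits it as a reference. In it the median of the 1489 genes was -0.27 ± 0.0096 (bootstrap SD) against -1.35, a ratio of 0.202, and 87 of them were 2-fold lower. A smaller part of the fall stays open, since 78.5% of them were negative there; the median of all genes, 0.147 times theirs, decides nothing alone because normalisation would remove a common factor. Poor RNA stays open, and the rule set beforehand came out in its favour. That rule asked whether differences of 2 probe sets of the same gene correlated less here than in TAM-R on estrogen, by a fixed margin. They correlated at 0.175 ± 0.016 (bootstrap SD) across genes, against 0.742 ± 0.011 in TAM-R on estrogen. A further condition outside that rule, that every pair with this array lie below every pair without it, was not met. The correlation was 0.0936 in the TAM-R hormone pair without AMD3100 and 0.246 in MCF7 on estrogen, which lack the array with the high actin ratio. Those 2 pairs had a smaller spread over all genes (SD 0.46 and 0.42, against 0.79 here), so they are not a like comparison. In pairs without that array at an SD of 0.74 to 0.80, the correlation ran from 0.39 to 0.807. Host muscle for the muscle genes themselves stays open, since the 9 markers had a median of 0.075 but 7 of them lay under the level filter in both arrays, and so does a response of TAM-R to AMD3100 on tamoxifen, which was not tested separately.

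Genes called in the line effect lay near each other in the genome. Of 273, 106 had a called neighbour of the same sign within 5 tested genes, against a mean of 33.7 and a highest value of 64 in 10000 shuffles (permutation p = 0.0001, the smallest these can give). Regulation that neighbours share in any contrast is argued against as the whole cause. Adjacent genes correlated at 0.256 in the line effect, 0.0941 for hormone and 0.0714 for AMD3100, with a shuffle SD of 0.0098 for line. A part of it stays open, since the hormone and AMD3100 values also exceeded their shuffle SDs of 0.0098 and 0.01. With no called gene, the AMD3100 effect is a weak comparison. A difference in DNA copy number between the lines is a candidate explanation that the 106 neighbours fit, with no DNA measurement to test it. The longest run held 15 called genes among 21 neighbours, ELP2 to ACAA2, with a median of 1.75 higher in TAM-R, and a run of 9 among 22, NARS1 to ZNF407-AS1, had a median of -1.22.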

How the results depend on the processing

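Array quality weights, the actin covariate and the term for the hybridisation controls were chosen only after the results were seen. That term covers 3 of the 4 tamoxifen arrays, so it leaves the hormone effect to TAM-R on tamoxifen with AMD3100 against the estrogen arrays, and its values for hormone test nothing. For line, AMD3100 and the interactions it amounts to leaving out that array. Of the counts and agreements, 133 stayed within 1.5 times the original, or within their spread, and 59 moved further. The 133 include counts with no called gene that stayed without one, as for AMD3100 and the interactions. They are therefore no measure of how stable the line and hormone counts were, which are given below by setting. The cause of the moves was not tested, except that fewer arrays leave fewer residual degrees of freedom. Of the single genes and lists, 1890 values stayed on their side of the threshold with the same direction or with no call, 426 lost a call, 9 gained one and 6 turned direction. These totals, and those of the counts, include the hormone values of the hybridisation term. Signal over background limits genes near the lowest values, such as CYP1A1.

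For line (273 genes), the count was 18 with no level filter, 144 with the mean of all probe sets, 632 with all 2-way interactions, 113 with the factor alone, 1125 with array quality weights, 180 with the hybridisation term, and 23 to 469 with an array left out. For hormone (260 genes), it was 0 with no level filter, without the variance trend or with matched pairs. It was 567 at a level of 7, 8 with the mean of all probe sets, 397 after quantile normalisation, 482 with arrays at the same median, 1300 with all 2-way interactions, 119 with the factor alone, 2250 with array quality weights, 19 with the actin gap, and 0 to 1287 with an array left out; the hybridisation term, with 1 tamoxifen array left to compare, gave 440.

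For AMD3100 (0 genes), all 2-way interactions gave 1; for line by AMD3100 they gave 4, for line by hormone 1 and for hormone by AMD3100 24. For the last, the actin gap gave 3, the hybridisation term 1 and leaving out an array 0 to 1. Each count with all 2-way interactions rests on the 3-way term alone as residual spread. Called lists in the 3 effects went from 15 to 0 with an estimated correlation. In the line by AMD3100 interaction they went from 8 to 0 with an estimated correlation, 5 with the mean of all probe sets, 5 after quantile normalisation, 4 with array quality weights, 4 with the actin gap, 5 with the hybridisation term, and 4 to 9 with an array left out.

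Counts of 2-fold AMD3100 differences with the mean of all probe sets were 501 in MCF7 on tamoxifen, 1243 in TAM-R on tamoxifen, 166 in MCF7 on estrogen and 818 in TAM-R on estrogen. At a level of 7 they were 577 in MCF7 on tamoxifen, 137 in MCF7 on estrogen and 822 in TAM-R on estrogen, and with no filter 467 in MCF7 on estrogen. The test turned direction for hypoxia genes with AMD3100 without MCF7 on tamoxifen (median -0.037) or MCF7 on tamoxifen with AMD3100 (-0.14), in a range from -0.89 to -0.037 over all arrays left out. It turned for cell cycle genes without TAM-R on estrogen, in the AMD3100 effect (-0.13, in a range to 0.31) and the line by AMD3100 interaction (-0.41, in a range to 0.89). It turned for ribosomal genes in that interaction without TAM-R on tamoxifen with AMD3100 (-0.081, in a range from -0.52) and with the hybridisation term (-0.081); the cause was not tested.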

Other observations

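Markers of other cell types were mostly near the lowest values. Endothelial markers reached at most 4.48 and erythroid markers 3.76 on the log2 scale, with 0 of 12 and 0 of 6 measured. Of the leukocyte and macrophage markers 1 of 14 was measured (highest 5.88), of the adipocyte markers 1 of 7 (8.23), of the fibroblast markers 4 of 15 (9.71) and of the muscle markers 2 of 9 (10.65, from MB, myoglobin, which lay at 9.19 to 10.65 in all 8 arrays).

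Among fibroblast markers, SPARC was lower in TAM-R at -3.33 ± 0.36, while COL3A1, a fibrillar collagen, differed by -1.29 ± 0.43 (adjusted p = 0.15) and COL1A1 by 0.84 ± 0.25 (adjusted p = 0.126); these collagens were chosen after their values were seen. Cholesterol synthesis genes went both ways, with medians of -0.11 for line (6 positive and 11 negative), 0.15 for hormone (9 and 8) and -0.10 for AMD3100 (8 and 9). Members with the lowest p were TM7SF2, a sterol reductase, at 0.78 ± 0.19 for line (adjusted p = 0.0728), and for hormone DHCR7, another, at 0.76 ± 0.18 (adjusted p = 0.0572) and STARD4, a sterol carrier, at 1.72 ± 0.48 (adjusted p = 0.0719), from a low mean of 3.34 on tamoxifen. CXCR4 and AHR pathway members had medians of -0.19, 0.11 and -0.033, and immediate early genes 0.018, 0.047 and -0.055.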
